A study of Mus musculus with 20 samples.

How the data were processed

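Hepa1-6 is an established mouse hepatoma line, derived from a liver tumour of the C57L strain. Per the labels' protocols, the cells were moved to medium without growth factors 4 h before the start and then received 1 ng/ml of TGFβ1 or no addition. RNA was taken at 0, 1, 3, 6 and 10 h from biological duplicates, which gave 10 groups of 2 cultures. Biotinylated cRNA of each culture was hybridised to its own Affymetrix array, and 20 arrays were analysed. The labels call the treated 0 h sample equivalent to the untreated 0 h sample.

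The authors deposited a table of log2 expression values with 1 value per probe set and array. Per the submitters' processing notes, these values were made with RMA, which corrects the background, normalizes the arrays to each other by quantiles and sums the probes of a set into 1 value on the log2 scale. The software version, the chip description file and any genome build are not given in the sources used here. RMA compresses the differences of dim probe sets, and its quantile step removes a change that shifts most transcripts the same way, so every difference below is relative to the other transcripts on the array. No detection calls were used, and the level of the background is not known, so folds of genes whose lower group mean lies below the array medians may be limited by it. The scale was checked on the values, which ran from 1.44 to 14.7 with array medians between 5.15 and 5.21.

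The table held 45037 probe sets. The platform annotation named exactly 1 gene for 34945 of them, several genes for 932 and no gene for 9160; the last 2 kinds were left out of the gene tests. The probe sets with 1 gene stood for 18194 genes, of which 9009 had several probe sets. Each gene was represented by its probe set with the highest mean log2 value over all arrays. Of these genes, 162 symbols were not found in the RefSeq gene table of the assembly GRCm38.p6 and kept the name of the annotation. That table served for names only, since the authors' build was not given, and no coordinates are printed. The table held 0 control probe sets, so RNA integrity could not be read from signals at the 3' and 5' ends of a transcript.

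The correlation between the duplicates of a group ran from 0.9958 to 0.9971 over all probe sets, and at most 0.04% of the values were identical in a pair of duplicates. No arrays were taken to be the same hybridisation. The number of arrays limits the precision: with 2 per group, the median standard error of a difference was 0.13 on the log2 scale.

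Differences were tested with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 20 arrays, which gives each gene 1 estimate of its spread with 10 residual degrees of freedom, and variances were moderated with a trend on the mean level (eBayes). P-values were adjusted by the Benjamini-Hochberg method over the 18194 genes within each comparison, and 0.05 was the threshold. The comparisons were treated against untreated cells at each time, the mean of the treated-minus-untreated differences over 1, 3, 6 and 10 h, the differences of that effect between times, and untreated cells at each later time against untreated cells at 0 h. Errors given with ± are standard errors of the log2 difference (SE) or standard deviations of duplicates (SD, n = 2). A fold is 2 raised to the log2 difference. For treated cells, rose and fell mean higher and lower than in untreated cells of the same time, not than at 0 h.

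Gene groups were tested with 41 lists that hold 1037 members, 976 of which were measured. They cover signalling pathways, transcription factor targets, metabolism, the cell cycle, apoptosis, hepatocyte functions, matrix and adhesion, and markers of other liver cell types. They were tested with limma's camera, which asks whether a list's genes are shifted against all other genes, with a preset correlation of 0.01 between genes and again with a correlation estimated from the data; p-values were adjusted over the 41 lists within a comparison. Fry, which tests whether a list's genes move on balance in 1 direction and makes no comparison with other genes, was run beside it. Members were counted as higher or lower after adjustment over all genes and also adjusted over the list alone. A gene can belong to several lists, as Ccn2 does to those of SMAD and YAP/TEAD targets, so calls of such lists are not independent.

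The groups, the comparisons, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except that the only difference between times fixed then was that of 10 h and 1 h. All other differences between times were added later. At each time, the rule named the 10 largest rises and the 10 largest falls among genes past the threshold whose treated arrays both lay beyond both untreated arrays, leaving out unnamed gene models. It added up to 3 members past the threshold, lowest adjusted p first, from each of the 6 lists with the highest share of changed members among lists with at least 5 measured members. It also named 5 genes at every time whatever their test; 1 of the 5 is not reported here. For untreated cells, the 10 largest rises and falls at 10 h against 0 h were named under the same conditions. The rule gave 168 values of 110 genes. Where a gene outside the rule is named, the text says so. The probe sets used for Ccn1, Ldlrad4, Slco4a1, Lmcd1, Nrep, Rrm2, Slco1b2, Ugt2b34 and Mt1 carry an ID that marks possible hybridisation to other transcripts.

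The steps were tested on simulated data that kept the level and the residual spread of each gene, in which 50 genes were shifted by each of 4 sizes. For treated against untreated cells at 1 h, limma recovered 10% of the genes shifted by 0.25 on the log2 scale, 50% of those shifted by 0.5, 94% of those shifted by 1 and 98% of those shifted by 2, with 6 false calls among 132. For the effect averaged over 4 times, the shares were 42%, 96%, 100% and 100%, with 7 false calls among 176. For the difference of the effect between 10 h and 1 h they were 10%, 38%, 86% and 100%, and for untreated cells at 10 h against 0 h they were 16%, 62%, 96% and 100%. Far fewer genes were shifted than were called in the data: for untreated cells at 10 h the simulation gave 146 calls and the data 4742. The adjustment was therefore stricter in the simulation, and these shares need not hold for the real comparisons. Camera called 0 of 40 random lists in the simulated 1 h comparison. The simulated noise was independent between genes, so this cannot show how often camera calls lists of correlated genes.

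The alternatives were a further quantile normalization, centring each array on its median, testing only genes above the median level, the mean of a gene's probe sets, every probe set on its own, fits to the compared arrays alone, variances moderated without a trend, array weights, the replicate number as a block, untreated 0 h as the control of all treated groups, the 4 arrays of 0 h as 1 group, and leaving out each array in turn.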

Results

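Expression was measured on 20 arrays of Hepa1-6 mouse hepatoma cells, kept without growth factors and either treated with 1 ng/ml TGFβ1 or left untreated for 0, 1, 3, 6 and 10 h, in duplicate cultures. TGFβ1 is a cytokine that signals through receptor kinases and SMAD transcription factors. The design sets each treated time beside untreated cells of the same time, and asks which transcripts TGFβ1 changes and when. The first principal component held 27.8% of the variance between arrays and the second 22.1%.

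Treated and untreated cells at 0 h, which the labels call equivalent, differed in 0 of 18194 genes by limma after adjustment. Without adjustment, 740 genes (4.07%) had p under 0.05. The 0 h comparison involves no time under treatment, and the adjustment sets a stricter cutoff where few genes differ. Its 0 calls therefore do not give the number of false calls at later times.

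After 1 h of TGFβ1, direct targets and feedback regulators of SMAD signalling and immediate early transcription factors were strongly higher. The largest rise was that of Klf10, a TGFβ-inducible zinc finger factor, at 11.9-fold (11.67 ± 0.11 against 8.10 ± 0.03, SD, n = 2; adjusted p = 3.73e-18). Smad7, an inhibitory SMAD that feeds back on the receptor, was 5.48-fold higher (log2 difference 2.45 ± 0.07, SE), and Skil, which encodes the SMAD corepressor SnoN, was 4.82-fold higher (2.27 ± 0.07, SE). Gadd45b rose 10.7-fold, Gadd45g 5.82-fold, Bhlhe40 7.39-fold, and the growth factor gene Pdgfb 9.13-fold. The proto-oncogene Myc was 2.26-fold lower (−1.18 ± 0.06, SE, adjusted p = 3.31e-12). The chemokine genes Cxcl5 and Cxcl2 were 4.44-fold and 4.39-fold lower, and Ppp1r3c, which targets protein phosphatase 1 to glycogen, was 2.96-fold lower.

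Of the 28 measured early SMAD targets and feedback genes, 15 rose at 1 h, 0 fell and 13 did not pass the test; adjusted over the list alone, 19 rose and 1 fell (camera, adjusted p = 3.18e-53, and 3.00e-07 with an estimated correlation). Of the 32 immediate early genes of the AP-1 and EGR kind, 21 rose and 2 fell, or 25 and 4 adjusted over the list alone (adjusted p = 7.08e-06 with an estimated correlation). Junb (8.43-fold), Jun (3.15-fold) and the phosphatase gene Dusp2 (7.38-fold) were among them. Of 19 YAP/TEAD targets 7 rose and 0 fell, or 11 and 0 adjusted over the list alone, with Ccn2 at 6.25-fold, Ccn1 at 3.93-fold and Nuak2 at 1.98-fold (adjusted p = 6.32e-04 with an estimated correlation). Ccn2 is also a member of the SMAD list, so the calls of these lists are not independent at this or later times. Of 15 targets of the BMP-activated SMADs, 5 rose and 0 fell, also adjusted over the list alone (adjusted p = 8.56e-04 with an estimated correlation). Those 5 were Id1 (3.47-fold), Id2 (5.05-fold), Id3 (3.48-fold), which encode inhibitors of basic helix-loop-helix factors, and Smad6 and Atoh8, named after their values were seen, with log2 differences of 1.86 and 0.88.

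Of the 7 CDK inhibitor genes, 3 rose and 0 fell at 1 h, also adjusted over the list alone: Cdkn2b by 1.63-fold, Cdkn1b by 1.49-fold and Cdkn1a by 1.18-fold. The list was called higher (adjusted p = 0.00256, and 0.0256 with an estimated correlation) although its median difference was −0.05. The call of Cdkn1a (adjusted p = 0.0416) was lost without either treated array at 1 h, at 0.277 without replicate 1 and 0.120 without replicate 2, and at 0.386 without replicate 1 of the untreated arrays. It was also lost with a further quantile normalization (0.123), every probe set tested (0.0687), a fit to the compared arrays alone (0.0766), no variance trend (0.227) and array weights (0.0843). Of 28 genes for growth factors and receptor tyrosine kinase ligands 7 rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p = 6.32e-04 with an estimated correlation). Of 24 FOXO targets and starvation genes 4 rose and 3 fell, or 7 and 3 adjusted over the list alone; Ddit4, an inhibitor of mTORC1 signalling, was 2.17-fold higher, Bcl6 2.05-fold higher and Txnip 1.56-fold lower (adjusted p = 0.0627 with an estimated correlation). Of 27 integrated stress response genes 5 rose and 0 fell, also adjusted over the list alone, with a median of −0.01 and a mean of 0.13 (adjusted p = 0.127 with an estimated correlation).

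In all, 407 genes differed at 1 h, 348 higher and 59 lower, and 58 rose and 5 fell at least 2-fold. Camera called 20 of the 41 lists, all of them higher, and 11 of these calls held with an estimated correlation. The remaining large falls were those of Gdap10 (2.01-fold), Flrt3 (1.82-fold), Zc3h12c (1.76-fold), Otud1 (1.64-fold) and Zfp54 (1.57-fold). The calls of Otud1 and Zfp54 each rested on 1 array: the adjusted p was 0.0784 for Otud1 without replicate 1 of the untreated arrays and 0.0865 for Zfp54 without replicate 1 of the treated arrays. With the mean of its probe sets, Zfp54 differed by −0.05 (adjusted p = 0.942). With a further quantile normalization 322 genes were higher and 102 lower, and with each array centred on its median 350 and 43. Against untreated cells at 0 h instead of 1 h, 466 genes were higher and 169 lower; with every probe set tested on its own, 663 probe sets passed.

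**Figure D1:**
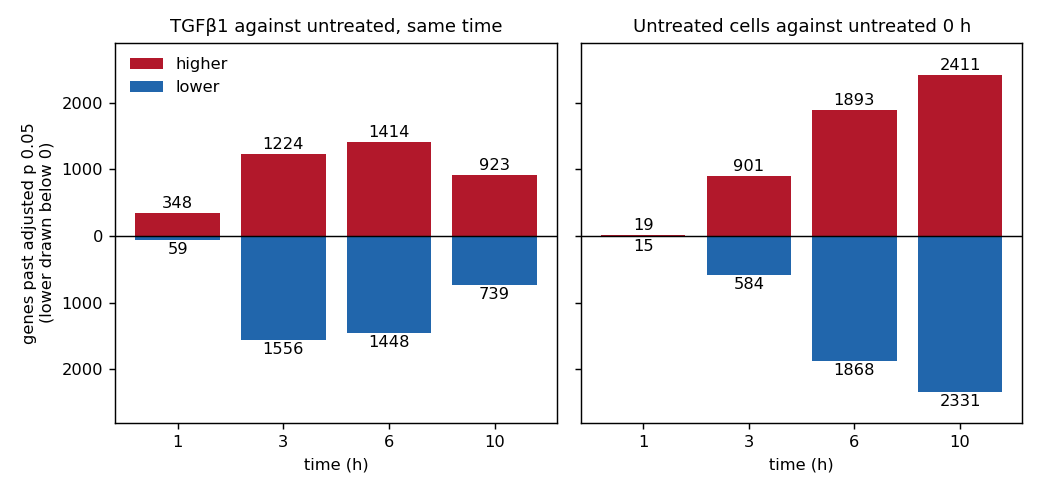
Number of genes past an adjusted p of 0.05 (vertical axis, higher above 0 and lower below 0) at each time in hours, for TGFβ1-treated against untreated cells of the same time (left) and for untreated cells against untreated cells at 0 h (right). The TGFβ1 bars rise from 348 higher genes at 1 h to 1414 at 6 h and stand at 923 at 10 h, while the bars of untreated cells grow up to 10 h.

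After 3 h, the genes with the largest differences were largely other ones. Ldlrad4, whose product restrains TGFβ receptor signalling, was 12.8-fold higher (6.98 ± 0.17 against 3.30 ± 0.12, SD, n = 2; adjusted p = 3.88e-13), the sulfotransferase gene Chst8 9.18-fold, Ccn2 9.11-fold, Skil 8.33-fold and the lysosomal membrane gene Dram1 8.11-fold. The untreated value of Ldlrad4 lies far below the array medians, so its fold may be limited by the background. Sertad4 (7.88-fold), Pdgfb (7.86-fold), Pstpip1 (6.86-fold), Spsb1 (6.73-fold) and Ccdc68 (6.61-fold) followed. The chemokine genes Cxcl3, Cxcl5 and Cxcl2 were 6.43-fold, 4.97-fold and 3.78-fold lower. Ppp1r3c was 4.19-fold lower, the receptor gene Calcrl 4.07-fold and the transporter gene Slco4a1 3.64-fold. Myot (3.56-fold), Sgk2 (3.31-fold), Lcorl (3.06-fold) and Rab20 (2.98-fold) were lower as well.

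Genes of sterol synthesis and other SREBP2 targets were lower than in untreated cells at 3 h: of 20 measured, 16 fell and 0 rose, or 17 and 0 adjusted over the list alone. The median difference was −0.33 (camera, adjusted p = 6.69e-11; adjusted p = 0.0557 with an estimated correlation). Msmo1 was 1.82-fold lower, Pmvk 1.52-fold and Idi1 1.37-fold, all enzymes of the pathway. Of 23 p53 targets, 17 fell and 1 rose, or 18 and 1 adjusted over the list alone, with a median of −0.36 (adjusted p = 6.69e-11, and 0.00870 with an estimated correlation). The BH3-only gene Pmaip1 was 1.68-fold lower, the antiproliferative gene Btg2 1.58-fold and the DNA repair gene Ercc5 1.54-fold.

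Of the 28 SMAD targets, 18 were higher and 0 lower at 3 h, or 19 and 0 adjusted over the list alone (adjusted p = 8.06e-06 with an estimated correlation). Bhlhe40 was 4.98-fold, Klf10 2.87-fold and Smad7 2.81-fold higher. Of 19 YAP/TEAD targets 9 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0264 with an estimated correlation), with Ccn1 at 2.96-fold and Nuak2 at 2.05-fold. Of 22 integrin and focal adhesion genes 7 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00870 with an estimated correlation). These 3 lists and the p53 targets were the 4 of 41 called with an estimated correlation, out of 14 with the preset one. Of 32 immediate early genes 12 rose and 9 fell, or 13 and 9 adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.0657); Junb was 4.66-fold and Dusp2 3.23-fold higher, and Dusp5 2.08-fold lower. Of 24 FOXO targets 7 rose and 7 fell, or 8 and 9 adjusted over the list alone, with Ccng2 1.88-fold and Ddit4 1.74-fold higher and Irs1 1.63-fold lower (adjusted p = 0.889).

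The preset test also called lower the list of MYC and ribosome biogenesis targets, named ribosome biogenesis genes below. Of its 29 genes 1 rose and 8 fell, or 1 and 12 adjusted over the list alone (adjusted p = 0.0975 with an estimated correlation). It called lower interferon stimulated genes, of which 1 rose and 10 fell of 25, also adjusted over the list alone (adjusted p = 0.0869 with an estimated correlation). It called lower hypoxia and glycolysis genes, of which 3 rose and 8 fell of 26, or 3 and 9 adjusted over the list alone (adjusted p = 0.0975 with an estimated correlation). It called higher the receptors, ligands and SMADs of the TGFβ family, of which 8 rose and 4 fell of 26, or 8 and 5 adjusted over the list alone, with a median of −0.03 and a mean of 0.15 (adjusted p = 0.0491, and 0.0869 with an estimated correlation). That call was also lost without replicate 2 of the treated arrays (0.132), without replicate 1 of the untreated arrays (0.0760), with a further quantile normalization (0.0532), without the variance trend (0.110), with the compared arrays alone (0.0784) and with array weights (0.0511). In all, 2780 genes differed at 3 h, 1224 higher and 1556 lower, with 155 up and 77 down at least 2-fold. Of the 348 genes higher at 1 h, 262 were also higher at 3 h, where 23.4 would be shared by independent lists. Another 20 of the 348 were lower at 3 h (29.8 for independent lists). The comparisons share no arrays, but they share 1 estimate of spread per gene. Calls at different times are therefore not independent, here and at later times, and the counts for independent lists are only a rough reference.

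After 6 h, Fam210b was 10.4-fold higher (11.33 ± 0.05 against 7.95 ± 0.05, SD, n = 2; adjusted p = 8.06e-18), Dram1 8.32-fold and the troponin gene Tnnt2 8.25-fold. Lmcd1 (8.11-fold), P2ry14 (7.95-fold), Ccn2 (7.81-fold), Ctla2b (7.07-fold), Nrep (6.30-fold) and the serine protease gene Htra1 (6.26-fold) were higher, as was Cps1, the first enzyme of the urea cycle, at 7.17-fold (6.37 ± 0.02 against 3.52 ± 0.11, SD, n = 2). The untreated value of Cps1 lies far below the array medians, so its fold may be limited by the background. The largest falls were those of Myot (4.15-fold), Sntb1 (3.76-fold) and the angiopoietin gene Angpt1 (3.70-fold). Ugt2b35 was 3.27-fold, Cyp1a1 3.07-fold and Slco1b2 3.00-fold lower. Of 42 genes of hepatocyte metabolism and cytochrome P450, 2 rose and 6 fell, or 3 and 6 adjusted over the list alone, and the list was not called (adjusted p = 0.209). Among genes above the median level camera did call it, with a median of −0.27 at 6 h (adjusted p = 0.0490) and −0.25 at 3 h (adjusted p = 0.0421). Foxp2 (3.34-fold), Tmem71 (3.13-fold), Aqp11 (3.09-fold) and Stc1 (3.08-fold) were also lower.

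Of the 20 sterol genes 18 were lower and 0 higher at 6 h, or 19 and 0 adjusted over the list alone, with a median of −0.43 (adjusted p = 7.02e-16, and 0.0149 with an estimated correlation). Pmvk was 1.68-fold, Dhcr7 1.51-fold and Ebp 1.36-fold lower. Of 37 genes of G1/S and DNA replication 21 fell and 1 rose, or 24 and 2 adjusted over the list alone, with a median of −0.23 (adjusted p = 0.0210 with an estimated correlation). The licensing factor Cdc6 was 1.43-fold lower, the histone mRNA binding gene Slbp 1.27-fold and the ribonucleotide reductase gene Rrm2 1.25-fold; with the mean of its probe sets, Slbp had an adjusted p of 0.0653. Of 26 hypoxia and glycolysis genes 14 fell and 0 rose, or 15 and 2 adjusted over the list alone (adjusted p = 0.00762 with an estimated correlation). Ankrd37 was 2.93-fold, the aldolase gene Aldoc 2.56-fold and Pdk1, a kinase that inhibits pyruvate dehydrogenase, 1.60-fold lower.

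Genes of the cytoskeleton and of adhesion were higher at 6 h. Of 30 actin and SRF target genes 11 rose and 1 fell, also adjusted over the list alone, and of 22 integrin and focal adhesion genes 10 rose and 0 fell, or 10 and 1 adjusted over the list alone (both adjusted p = 0.00762 with an estimated correlation). SMAD targets stood at 18 higher and 0 lower of 28, also adjusted over the list alone, with Skil at 5.87-fold, Bhlhe40 at 3.17-fold, Smad7 at 2.14-fold and Klf10 at 1.78-fold (adjusted p = 2.73e-05 with an estimated correlation). Of 19 YAP/TEAD targets 9 rose and 0 fell, or 10 and 1 adjusted over the list alone (adjusted p = 0.00762 with an estimated correlation). Of the 15 BMP targets 0 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.0490, and 0.116 with an estimated correlation): Id1 was 1.12-fold lower, and Id2, Id3, Hamp and Atoh8, named after their values were seen, had log2 differences of −0.75, −1.40, −0.73 and −0.68. The list also lost its call with a further quantile normalization (0.0793), without the variance trend (0.0778), without replicate 2 of the treated arrays (0.0645) and without replicate 1 of the untreated arrays (0.105). The call of Id1 at 6 h (adjusted p = 0.0152) was lost at 0.110 without replicate 1 of the treated arrays, and at 0.0679 and 0.0773 without replicate 1 and replicate 2 of the untreated arrays, and at 0.0874 without the variance trend.

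Among the 7 CDK inhibitors at 6 h, Cdkn2b was 1.62-fold higher while Cdkn2d and Cdkn2c were 1.82-fold and 1.47-fold lower; 1 rose and 3 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.303). Of 32 immediate early genes 10 rose and 7 fell, or 11 and 7 adjusted over the list alone, with Junb at 2.66-fold and Jun at 1.60-fold higher and Dusp5 at 1.66-fold lower (adjusted p = 0.198). Of 23 p53 targets 8 fell and 1 rose, or 11 and 1 adjusted over the list alone (adjusted p = 6.95e-04, and 0.0766 with an estimated correlation). In all, 2862 genes differed at 6 h, 1414 higher and 1448 lower, and 126 rose and 49 fell at least 2-fold. With a further quantile normalization 1342 were higher and 1736 lower, and with each array centred on its median 1429 and 1170. Of 41 lists camera called 20, and 11 with an estimated correlation. Of the 1224 genes higher at 3 h, 759 were higher at 6 h (95.1 for independent lists), and of the 1556 lower genes, 691 were lower (124 for independent lists).

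**Figure D2:**
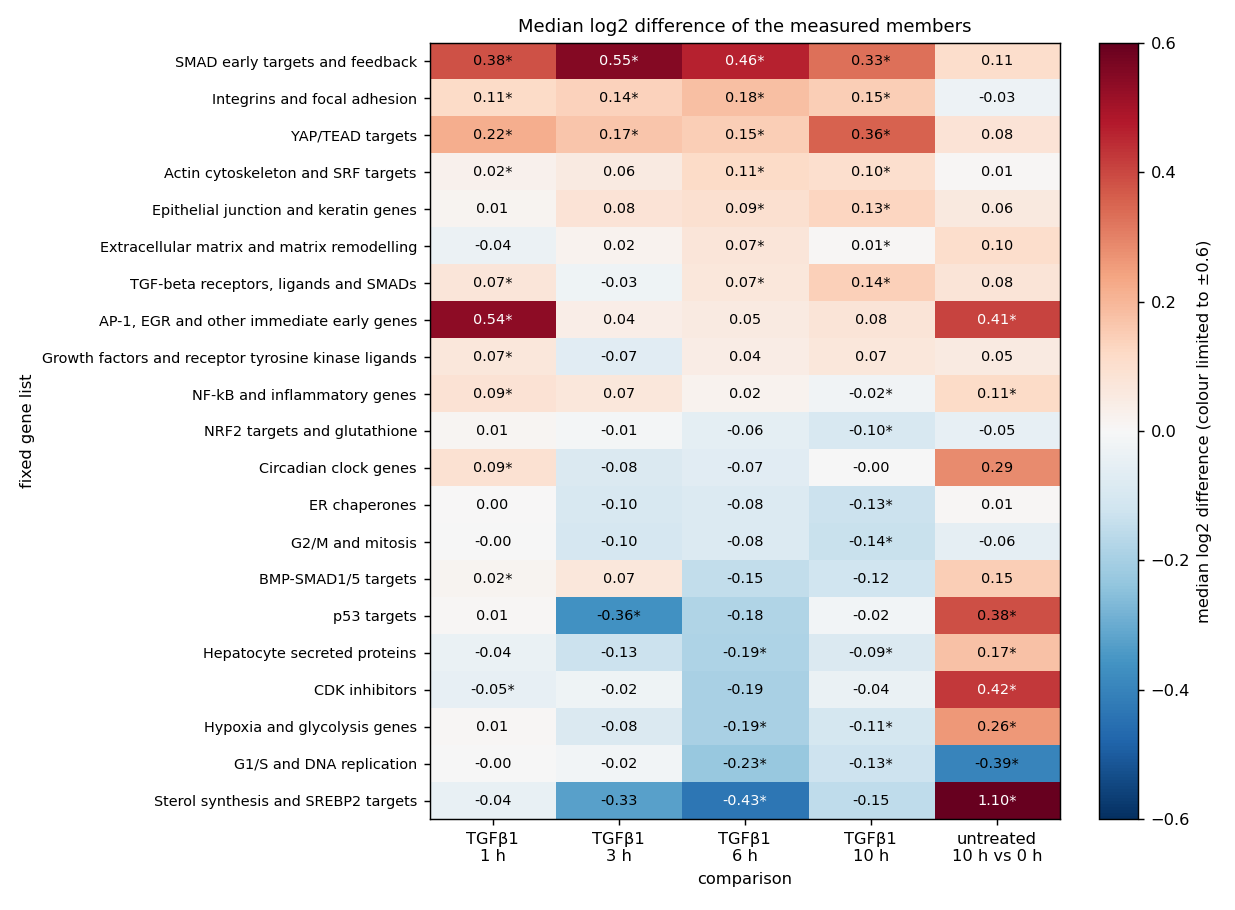
Median log2 difference of the measured members of each fixed gene list (vertical axis) in each comparison (horizontal axis), for lists called at 1 or more of the TGFβ1 times; a star marks an adjusted p under 0.05 in camera with both the preset and the estimated correlation. SMAD targets stayed above 0 at all 4 times (0.38, 0.55, 0.46 and 0.33), while sterol genes lay lowest at 6 h with −0.43 and at 1.10 in untreated cells at 10 h against 0 h.

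After 10 h, Fam210b was 6.84-fold higher (10.43 ± 0.12 against 7.65 ± 0.03, SD, n = 2; adjusted p = 5.26e-16), Ctla2a 4.96-fold, Tnnt2 4.66-fold, Dram1 4.63-fold and Nrep 4.55-fold. Ctla2b (4.40-fold), Serpinb7 (4.34-fold), Ccn2 (4.28-fold), the teneurin gene Tenm4 (3.65-fold) and the sulfate donor synthase gene Papss2 (3.36-fold) were higher as well. The organic anion transporter gene Slco1b2, which hepatocytes use for uptake, was 5.02-fold lower (−2.33 ± 0.23, SE), and the glucuronosyltransferase genes Ugt2b35 and Ugt2b34 were 3.09-fold and 2.53-fold lower. Slco1b2 also rose in untreated cells by 10 h, so its 5.02-fold difference is not a fall of that size from 0 h. Fer1l6 (3.95-fold), Myot (2.80-fold), the coreceptor gene Tgfbr3 (2.42-fold), Foxp2 (2.33-fold), Stc1 (2.30-fold), Cxcl3 (2.30-fold) and Sntb1 (2.27-fold) were lower.

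Of the 28 SMAD targets 15 were higher and 2 lower at 10 h, or 19 and 2 adjusted over the list alone (adjusted p = 2.78e-04 with an estimated correlation); Skil was 3.31-fold, Sox4 1.34-fold, Smad7 1.34-fold and Klf10 1.29-fold higher. Id1 differed by 0.14 ± 0.05 (SE) and did not pass (adjusted p = 0.0740). It passed in 4 of the alternatives, with adjusted p = 0.0416 among genes above the median level, 0.0367 in a fit to the compared arrays alone, 0.0326 with array weights and 0.0456 with the replicate number as a block. Of 19 YAP/TEAD targets 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (adjusted p = 0.00755 with an estimated correlation), with Igfbp3 at 2.47-fold and Ankrd1 at 1.56-fold. Actin and SRF targets rose in 9 of 30 with 0 lower, or 12 and 0 adjusted over the list alone (adjusted p = 0.00755 with an estimated correlation). Integrin and focal adhesion genes rose in 6 of 22 with 0 lower, or 8 and 0 adjusted over the list alone (adjusted p = 0.0104 with an estimated correlation). Among 28 growth factor genes 6 rose and 5 fell, also adjusted over the list alone, with Pdgfb 1.89-fold and Pdgfc 1.80-fold higher and Tgfa 1.52-fold lower (adjusted p = 0.573).

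Sterol genes were lower in 8 of 20 with 0 higher at 10 h, or 9 and 0 adjusted over the list alone (adjusted p = 1.06e-06; adjusted p = 0.0716 with an estimated correlation); Pmvk was 1.64-fold, Tm7sf2 1.45-fold and Ebp 1.22-fold lower. Hypoxia and glycolysis genes were lower than in untreated cells in 9 of 26 and higher in 1, or 9 and 2 adjusted over the list alone (adjusted p = 0.0166 with an estimated correlation). Aldoc was 2.11-fold, Ankrd37 1.74-fold and Pdk1 1.34-fold lower. Aldoc and Ankrd37 rose by larger folds in untreated cells by 10 h, so in treated cells they still lay above 0 h. Genes of G2/M and mitosis fell in 9 of 32 and rose in 0, or 12 and 0 adjusted over the list alone (adjusted p = 0.0241 with an estimated correlation), and G1/S genes fell in 11 of 37 and rose in 2, or 18 and 4 adjusted over the list alone (adjusted p = 0.0359). Of 29 ribosome biogenesis genes, called lower at 3 h, 3 rose and 1 fell at 10 h, also adjusted over the list alone. The list was called higher at 10 h (adjusted p = 0.00961, and 0.137 with an estimated correlation), and among genes above the median level the call was lost (0.0863). Its preset call at 6 h was lost with centred arrays (camera, adjusted p = 0.0677) and with the mean of probe sets (0.202). Of 33 NF-κB and inflammatory genes 10 fell and 2 rose, or 11 and 3 adjusted over the list alone, with a median of −0.02 (adjusted p = 0.0287 with an estimated correlation). The chemokine genes Cxcl15 and Cxcl10 were 2.25-fold and 2.24-fold lower, and Lcn2, which encodes lipocalin 2, was 3.21-fold higher (4.91 against 3.22 ± 0.68, SD, n = 2), a fold that the background may limit in the same way.

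In all, 1662 genes differed at 10 h, 923 higher and 739 lower, and 37 rose and 25 fell at least 2-fold. The balance of directions depended on the scaling: with a further quantile normalization 822 were higher and 901 lower, and with each array centred on its median 873 and 600. The count was 1099 without the variance trend. It fell when any 1 array at 10 h was left out, by a larger share than for TGFβ1 at 1, 3 or 6 h. Each of the 4 arrays lowered it and such fits hold fewer arrays, so this does not show that it rested on a single one. Of the 1414 genes higher at 6 h, 627 were higher at 10 h (71.7 for independent lists), and of the 1448 lower genes, 514 were lower (58.8). Camera called 21 of 41 lists, and 14 with an estimated correlation.

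Markers of other liver cell types were tested in the same way. Stellate cell and fibroblast, endothelial, macrophage and lymphocyte lists were not called at 1, 3, 6 or 10 h. At 6 h their adjusted p was 0.619, 0.619, 0.898 and 0.728. The cholangiocyte and progenitor list was called higher at all 4 times with the preset correlation and at 0 of them with an estimated one (adjusted p = 0.0543, 0.0869, 0.119 and 0.0716); 1, 4, 4 and 3 of its 13 members rose, and 1 fell at 6 h, where its median was −0.04. Adjusted over the list alone, 4, 4, 4 and 3 rose. Its preset call was also lost at 1 h without replicate 2 of the treated arrays (0.0732) or replicate 1 of the untreated arrays (0.108), at 3 h without replicate 1 of the treated arrays (0.0561) and with the mean of probe sets (0.0719), and at 6 h without replicate 2 of the treated (0.114) or of the untreated arrays (0.102). At 6 h it was lost as well with a further quantile normalization (0.0537), centred arrays (0.0555), the compared arrays alone (0.0981) and no variance trend (0.0778).

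Over the whole course, 4592 genes were called at 1 or more times, 2444 of them at 1 time and 139 at all 4. Of these 139, 126 were higher and 9 lower throughout. The effect averaged over 1, 3, 6 and 10 h was past the threshold for 4090 genes, 1986 higher and 2104 lower. This split depended on the scaling, with 1773 higher and 2604 lower after a further quantile normalization and 2051 and 1801 with each array centred on its median. The largest absolute difference fell at 1 h for 196 of the 4592 genes, at 3 h for 1856, at 6 h for 1777 and at 10 h for 763. For Smad7 the log2 differences were 2.45, 1.49, 1.10 and 0.42 at 1, 3, 6 and 10 h (SE 0.07), for Klf10 3.57, 1.52, 0.83 and 0.37 (SE 0.07), and for Skil 2.27, 3.06, 2.55 and 1.73 (SE 0.07).

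A direct test of the difference between the effects at 10 h and 1 h was past the threshold for 732 genes, 295 with the more positive effect at 10 h and 437 at 1 h. Without replicate 1 of the treated arrays at 10 h this count was 447, without replicate 1 and replicate 2 of the untreated arrays at 10 h it was 437 and 485, and without the variance trend it was 422. Of the 41 lists 20 were called for this difference, 3 with the more positive effect at 10 h and 17 at 1 h, and 13 calls held with an estimated correlation; p53 targets were not called (adjusted p = 0.301). The other differences between times were added after the data were seen. Between 3 h and 1 h 1166 genes differed in their effect, between 6 h and 3 h 828 and between 10 h and 6 h 444. The list tests of 10 h against 3 h and of 6 h against 1 h were chosen after the effects at single times were seen. For 6 h against 1 h 22 of 41 lists were called, 4 with the more positive effect at 6 h and 18 at 1 h, and 14 held with an estimated correlation. For 10 h against 3 h 9 lists were called, and the 4 that held with an estimated correlation were p53 targets, SMAD targets, ribosome biogenesis genes and NF-κB and inflammatory genes. The effect on p53 targets was more positive at 10 h than at 3 h, with a median difference of 0.43, 10 members higher and 0 lower of 23 (adjusted p = 8.09e-09, and 0.0216 with an estimated correlation). For SMAD targets the effect was more positive at 3 h, with a median of −0.49 for 10 h minus 3 h (adjusted p = 2.91e-05 with an estimated correlation). For ribosome biogenesis genes the median was 0.20, with 8 members higher and 0 lower of 29 (adjusted p = 8.45e-07, and 0.0352 with an estimated correlation), and for NF-κB and inflammatory genes −0.14, with 4 higher and 8 lower of 33 (adjusted p = 0.00191, and 0.0216).

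**Figure D3:**
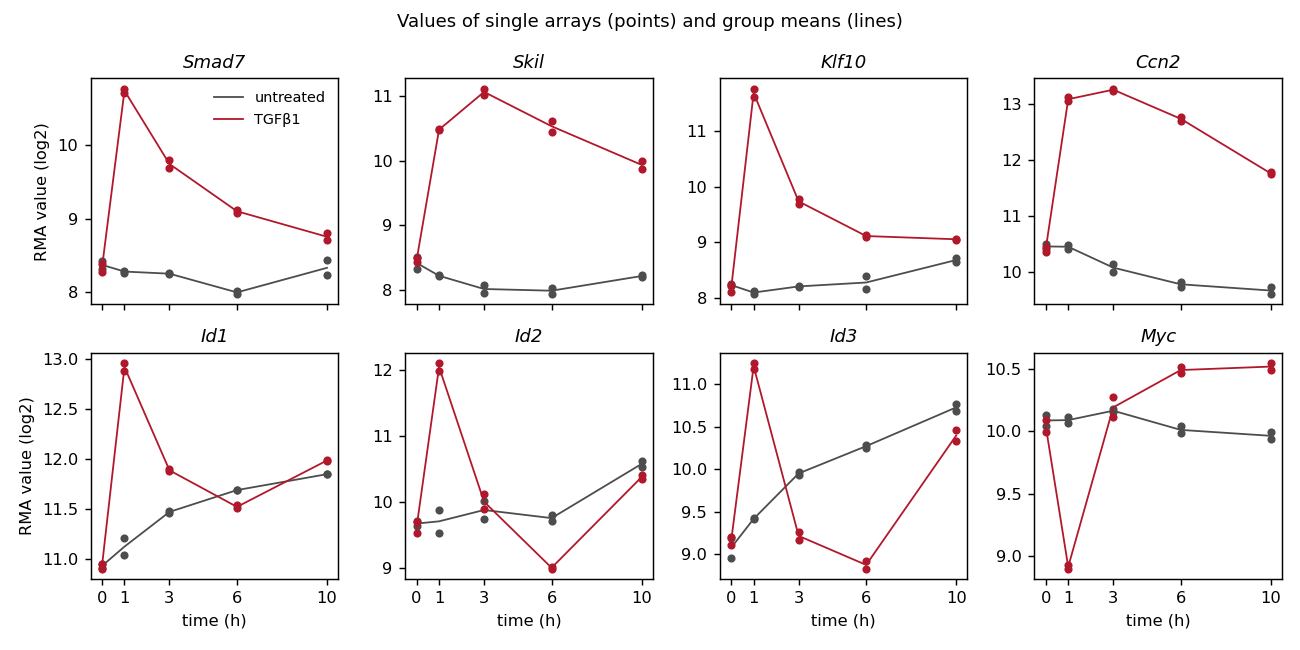
RMA values on the log2 scale (vertical axis) of 8 genes against time in hours, with 1 point per array and lines through the means of duplicates, for TGFβ1-treated (red) and untreated (grey) cells. Smad7, Klf10, Id1, Id2 and Id3 are highest in treated cells at 1 h, Skil and Ccn2 at 3 h, and Myc is lowest at 1 h.

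Untreated cells also changed with time in medium without growth factors, and these changes form the background of every treated group. At 10 h against 0 h, hypoxia, glycolysis and sterol genes were higher. Bnip3, which encodes a mitophagy receptor, was 6.38-fold higher (12.39 ± 0.03 against 9.71 ± 0.21, SD, n = 2; adjusted p = 3.32e-14), Aldoc 6.21-fold and Ankrd37 5.00-fold, and the sterol genes Mvd and Tm7sf2 3.55-fold and 3.24-fold. Unc13c (4.67-fold), the acetyl-CoA synthetase gene Acss2 (3.53-fold), Slco1b2 (3.31-fold), Id3 (3.15-fold) and Lrp2bp (3.11-fold) were higher too. The metallothionein genes Mt2 and Mt1 were 21.0-fold (−4.39 ± 0.24, SE) and 5.33-fold lower. Elac1 (5.18-fold), P2ry14 (3.67-fold), Cyp1b1 (3.33-fold), Zkscan8 (3.14-fold), Pag1 (2.95-fold), Eef1akmt2 (2.93-fold), Htra1 (2.89-fold) and Ppip5k1 (2.88-fold) were lower.

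Of the 20 sterol genes 19 rose and 0 fell in untreated cells at 10 h, or 20 and 0 adjusted over the list alone, and their median stood at 0.84 at 3 h, 1.30 at 6 h and 1.10 at 10 h above 0 h (adjusted p = 0.00352 at 10 h with an estimated correlation). Of 26 hypoxia and glycolysis genes 16 rose and 0 fell at 10 h, or 16 and 2 adjusted over the list alone, and of 32 immediate early genes 20 rose and 1 fell, also adjusted over the list alone (both adjusted p = 0.00352 with an estimated correlation). Of 37 G1/S genes 30 fell and 3 rose, or 31 and 3 adjusted over the list alone, with a median of −0.39 (adjusted p = 0.00352). Of 23 p53 targets 17 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0107), and of 18 fatty acid synthesis genes 12 rose and 1 fell, or 13 and 1 adjusted over the list alone (adjusted p = 0.00607). Of 29 ribosome biogenesis genes 15 fell and 1 rose, or 19 and 2 adjusted over the list alone (adjusted p = 0.0210 with an estimated correlation).

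The number of genes that differed from 0 h in untreated cells was 34 at 1 h, 1485 at 3 h, 3761 at 6 h and 4742 at 10 h, where 2411 were higher and 2331 lower. At 10 h the split was 2619 and 2256 after a further quantile normalization and 2121 and 2369 with each array centred on its median. These 4 comparisons share the untreated arrays of 0 h. The counts at 1 h and 3 h moved by over 1.5 times without any 1 array: without replicate 1 and replicate 2 of 0 h they were 4 and 13 at 1 h and 840 and 639 at 3 h, and without replicate 1 and replicate 2 of the later time 21 and 7 at 1 h and 750 and 620 at 3 h. At 1 h no more than 83 genes passed in any setting, and 0 passed in a fit to the compared arrays alone; in the fit to all arrays 1454 genes had an unadjusted p under 0.05.

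**Figure D4:**
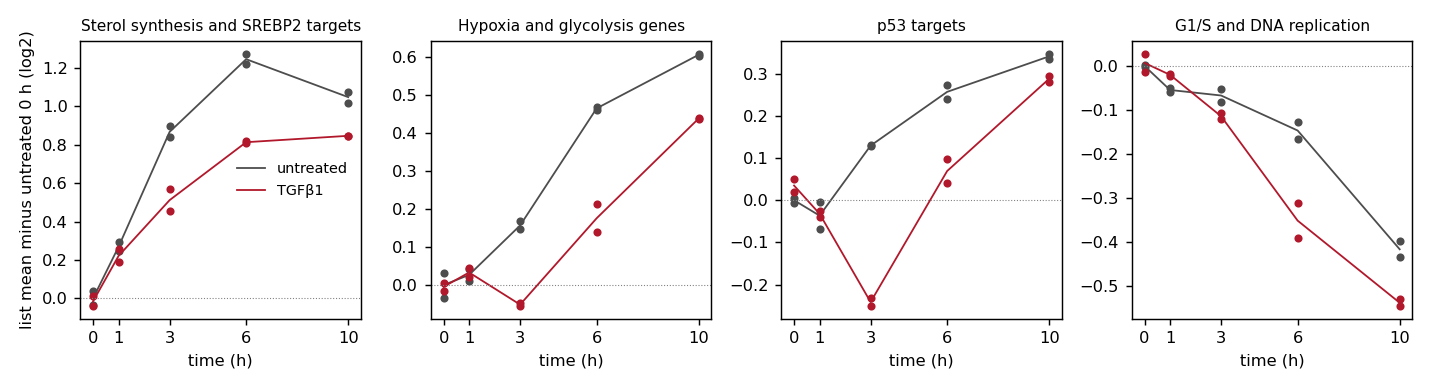
Mean of the members of 4 gene lists on each array minus their mean in untreated cells at 0 h (log2, vertical axis) against time in hours, with 1 point per array and lines through the means of duplicates, for TGFβ1-treated (red) and untreated (grey) cells. Sterol genes rise in both but stay lower with TGFβ1 from 3 h on, p53 targets dip below 0 with TGFβ1 at 3 h, and G1/S genes fall in both.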

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

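Of the tests below, all differences between times other than 10 h and 1 h were added after the data were seen, and those of a slower untreated time course, of untreated 3 h arrays out of place and of a rise of Id2 and Id3 in untreated cells alone were chosen after the result was seen. The genes and counts in this paragraph and the next 3 were singled out because the effect of TGFβ1 differed between time points by a direct test of the difference. Between 10 h and 1 h 732 genes differed in this way, between 3 h and 1 h 1166, between 6 h and 3 h 828, and between 10 h and 6 h 444. Single genes are given for 10 h against 1 h, and for any pair of times where the gene was past the threshold in opposite directions.

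Of the 97 genes named for TGFβ1, 66 differed between 10 h and 1 h, 43 with the more negative and 23 with the more positive effect at 10 h. Over all 18194 genes, 732 (4.02%) did. The naming rule picked genes for large effects at single times on the same arrays, so a higher share among them was built in. The log2 effect at 10 h minus that at 1 h was −3.20 for Klf10, −2.92 for Gadd45b, −2.75 for Dusp2, −2.60 for Junb, −2.54 for Id2, −2.52 for Gadd45g, −2.45 for Slco1b2, −2.28 for Bhlhe40, −2.27 for Pdgfb, −2.25 for Cxcl10, −2.13 for Id3 and −2.03 for Smad7. It was −1.82 for Fer1l6, −1.66 for Id1, −1.49 for Ugt2b35, −1.48 for Tgfbr3, −1.34 for Ugt2b34, −1.25 for Ccn1, −1.24 for Jun, −1.17 for Cxcl15, −1.16 for Foxp2, −1.15 for Myot, −1.14 for Ddit4, −1.12 for Sntb1 and −1.09 for Aqp11. Smaller values were −0.94 for Aldoc, −0.92 for Spsb1, −0.85 for Dusp5, −0.73 for Pmvk, −0.73 for Stc1, −0.67 for Cxcl3, −0.65 for Tgfa, −0.61 for Cdkn1b and −0.60 for Cdkn2d. Then came −0.54 for Ccn2, −0.54 for Skil, −0.53 for Cdkn2b, −0.50 for Tm7sf2, −0.48 for Cdkn2c, −0.48 for Nuak2, −0.44 for Btg2, −0.42 for Tmem71 and −0.30 for Rrm2.

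The effect was more positive at 10 h by 1.96 for Ctla2a, 1.91 for Serpinb7, 1.90 for Nrep, 1.76 for Tenm4, 1.73 for Myc, 1.71 for Lcn2, 1.52 for Fam210b, 1.40 for Ldlrad4, 1.34 for Cxcl2, 1.22 for P2ry14, 1.21 for Ctla2b, 1.12 for Igfbp3, 1.12 for Papss2 and 1.09 for Tnnt2. It was more positive by 0.96 for Dram1, 0.93 for Zc3h12c, 0.89 for Flrt3, 0.87 for Pdgfc, 0.84 for Gdap10, 0.75 for Ppp1r3c, 0.73 for Ccdc68, 0.55 for Txnip and 0.43 for Irs1.

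Among the named genes, 8 were past the threshold in opposite directions at 2 times. Id3 was above untreated cells at 1 h, with a log2 difference of 1.80, and below them at 6 h, with −1.40 (difference 3.20, adjusted p = 9.35e-15), Id2 had 2.34 and −0.75 at the same times (3.09, adjusted p = 3.67e-12), and Id1 1.80 and −0.17 (1.96, adjusted p = 3.98e-14). Myc went from −1.18 at 1 h to 0.56 at 10 h (1.73, adjusted p = 6.13e-12). Cxcl10 went from 1.76 at 3 h to −1.16 at 10 h (2.92, adjusted p = 2.10e-11), and Irs1 from −0.70 at 3 h to 0.21 at 10 h (0.91, adjusted p = 2.25e-09). Btg2 went from 0.36 at 1 h to −0.66 at 3 h (1.02, adjusted p = 3.40e-07), and Cdkn1a from 0.24 to −0.22 (0.46, adjusted p = 0.00139). The alternatives were run only for values given by the naming rule, so for most of these genes 1 side was not tested in this way. Untested sides include Id2 and Id3 at 6 h and Cdkn1a at 3 h (limma, adjusted p = 0.0145). Among the tested sides 2 were less firm. Cdkn1a at 1 h lost its call in 8 settings. Id1 at 6 h lost its call without replicate 1 of the treated arrays, without either untreated array and without the variance trend (limma, adjusted p = 0.0874).

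The 10092 probe sets that name no gene or several stand outside the gene tests and enter only where every probe set was tested on its own; they are given here as a signal in data that the gene comparisons do not use. In a fit to all 45037 probe sets, with p-values adjusted over all of them, 81 of the 10092 differed with TGFβ1 at 1 h, 373 at 3 h, 324 at 6 h and 164 at 10 h, and 0 at 0 h.

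Of the patterns below, only that of Id2 and Id3 was singled out by such a test; the others were chosen for weighing. The count of genes for the effect averaged over 1, 3, 6 and 10 h was set against other splits of the treatment labels within times. Among 100 splits drawn from 648 possible ones, 1 gave as many genes, the real one with 4090; the highest other gave 2014 and the median other 1. A split that puts treated and untreated arrays into the same group adds the TGFβ1 effect to the spread, which lowers its count. The other splits therefore do not show what chance alone would give, and no conclusion is drawn from them.

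Sterol genes lay below untreated cells at 3 and 6 h, though with an estimated correlation the call at 3 h was lost (adjusted p = 0.0557) while that at 6 h held (adjusted p = 0.0149). An odd array is not in line with the pairs of 1 treated and 1 untreated array, since all 8 list medians lay between −0.45 and −0.28 while duplicates differed by at most 0.10. A distortion tied to signal level is not in line with 0 of 10000 level-matched lists reaching as low a median at either time. A slower course of every change seen in untreated cells would put G1/S genes, with a median of −0.17 in untreated cells at 6 h, above untreated cells. Their median was −0.23. This 1 list cannot exclude a slower course in only part of the genes. Hypoxia genes and p53 targets also rose in untreated cells by 10 h and were lower with TGFβ1 at 6 h. Across all genes, the effects at 3 and 6 h correlated at −0.19 and −0.14 with the change of untreated cells at 10 h. The data are consistent with the hypothesis that TGFβ1 restrains the rise of sterol genes in this medium; no measurement of sterols or of SREBP2 is available to test it.

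p53 targets lay below untreated cells at 3 h. All 4 pairs of arrays had list medians between −0.38 and −0.36 while duplicates differed by at most 0.02, and 0 of 10000 level-matched lists had as low a median, so neither an odd array nor a level effect is consistent with the data. Untreated 3 h arrays that stand apart are not in line with the treated 3 h arrays against the 4 arrays of 0 h, where the median was −0.24 (camera, adjusted p = 4.39e-07), beside 0.01 between the 0 h groups. Other explanations were not tested, and no biological one was.

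Id2 and Id3 were above untreated cells at 1 h and below them at 6 h. An odd array is not in line with the 8 pairs of arrays at 6 h, the highest of which was −0.69, while duplicates differed by 0.10 or less. For Id2, a rise in untreated cells alone is not in line with treated cells at 6 h, which lay below untreated cells at 0 h with a log2 difference of −0.67 ± 0.10 (SE, adjusted p = 1.81e-05), with 3 of 3 probe sets below untreated cells at 6 h. For Id3 the test cannot tell: treated cells at 6 h lay at −0.20 ± 0.07 (SE, adjusted p = 0.0344) against 0 h, and untreated cells had risen by 1.20 (adjusted p = 1.08e-10), so neither written prediction was met. The bounds for Id2 and Id3 differed, and both were set after the result was seen.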

How the results depend on the processing

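The counts of genes past the threshold stayed within 1.5 times the reported ones in all 11 comparisons with a further quantile normalization, with only genes above the median level, with array weights and with the replicate number as a block. This holds for totals only: with the quantile normalization the lower genes at 1 h went from 59 to 102, and at 10 h higher and lower genes went from 923 and 739 to 822 and 901. The cause of these shifts was not tested. Both duplicates of a group received the same array weight, so that setting could not lessen the pull of 1 odd array. The duplicates showed no pairing of the same sign in all groups. Over 45 pairs of groups, the correlation of the duplicates' deviations ran from −0.20 to 0.21 with a median of 0.01, and 5 were above 0.1. Under the block the counts at 1, 3, 6 and 10 h rose from 407, 2780, 2862 and 1662 to 449, 2891, 3021 and 1788. Variation shared by arrays of 1 replicate number is therefore not excluded. For untreated cells at 1 h against 0 h the count of 34 became 21 with each array centred on its median, 4 with the mean of all probe sets, 0 with only the arrays compared and 83 with all 0 h arrays as 1 group, and the cause was not tested. With every probe set tested on its own, more units were tested and the counts were 663 at 1 h, 6593 for the averaged effect, and 10, 5839 and 7508 in untreated cells at 1, 6 and 10 h. Without the variance trend they were 1099 at 10 h, 422 for the difference between 10 h and 1 h, and 1 and 865 in untreated cells at 1 and 3 h; the cause was not tested. With untreated 0 h as the control, which adds the changes of untreated cells to the treated ones, they were 635 at 1 h, 4298 at 6 h and 5090 at 10 h.

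Leaving out 1 array leaves its group with 1, and that lone sample is assumed to vary like the other groups. The counts then ran from 325 to 351 at 1 h, 1975 to 2103 at 3 h, 2046 to 2250 at 6 h, 833 to 1112 at 10 h, 3656 to 4032 for the averaged effect and 437 to 594 for the difference between 10 h and 1 h. In untreated cells they ran from 4 to 21 at 1 h, 620 to 840 at 3 h, 2546 to 3028 at 6 h and 3526 to 3754 at 10 h; fewer arrays were used in each.

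Of 205 list results, 37 lost the call with an estimated correlation; fry gained 40 and reversed 1, the hepatocyte transcription factors at 3 h (median −0.00596), whose median lay near 0; the cause was not tested. Without 1 array, 777 of 820 list values, called or not, stayed on their side of the threshold, 35 lost a call and 8 gained one. Of 2153 values of the named genes, 2133 kept their direction and their side of the threshold, 16 lost the call, 4 gained it and 0 reversed.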

Other observations

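The single genes in this part were chosen after their values were seen. Of 44 extracellular matrix genes, 9 rose and 4 fell at 6 h and 12 rose and 1 fell at 10 h, or 12 and 4, and 13 and 2, adjusted over the list alone (adjusted p = 0.0294 and 0.0113 with an estimated correlation). At 6 h the call, made with the preset correlation, was lost without replicate 2 of the treated arrays (adjusted p = 0.0511). The fibronectin gene Fn1 differed by a log2 value of 0.46 ± 0.05 (SE) at 6 h and 0.63 at 10 h, the laminin gene Lamb1 by 1.18 ± 0.13 and 1.09, and Plat, which encodes tissue plasminogen activator, by 1.36 ± 0.06 and 0.72. Of 34 epithelial junction and keratin genes, 9 rose and 2 fell at 6 h and 8 rose and 1 fell at 10 h, also adjusted over the list alone (adjusted p = 0.0421 and 0.0166 with an estimated correlation). Cldn4, a tight junction gene, was higher by 1.81, 1.87, 1.69 and 0.97 at 1, 3, 6 and 10 h (SE 0.06). Of 20 EMT transcription factors and mesenchymal markers, 1 rose and 0 fell at 1 h, 4 and 0 at 3 h, 6 and 0 at 6 h and 6 and 1 at 10 h; adjusted over the list alone, 2 rose and 0 fell, then 4 and 1, 6 and 1, and 6 and 1. The list was not called at 1 or 3 h (adjusted p = 0.368 and 0.172), and its calls at 6 and 10 h (0.0105 and 0.00432) were lost with an estimated correlation (adjusted p = 0.119 and 0.0834). The 6 h call was also lost without replicate 2 of the treated arrays (0.0645). Snai1, a repressor of epithelial genes, was higher by 1.91 ± 0.18 (SE) at 1 h and differed by 0.44 ± 0.18 at 3 h (adjusted p = 0.127). Cdh2, the N-cadherin gene, was higher by 0.46 and 0.57 at 6 and 10 h (SE 0.07).

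Of 32 genes for proteins that hepatocytes secrete, 7 fell and 1 rose at 6 h and 6 fell and 1 rose at 10 h, or 8 and 1, and 9 and 1, adjusted over the list alone (adjusted p = 0.0402 and 0.0241 with an estimated correlation). The fibrinogen gene Fgb was lower, with log2 differences of −0.66, −0.78 and −1.09 at 3, 6 and 10 h (SE 0.09), and the albumin gene Alb was lower, with −0.39 and −0.49 at 6 and 10 h (SE 0.06). Of 25 pro-apoptotic genes, 2 rose and 0 fell at 1 h, 2 rose and 10 fell at 3 h, 3 and 4 at 6 h and 3 and 2 at 10 h; adjusted over the list alone, 3 rose and 1 fell, then 2 and 10, 4 and 5, and 3 and 2. The list was called higher at 1 h and lower at 3 h (adjusted p = 0.0366 and 0.0137), and both calls were lost with an estimated correlation (adjusted p = 0.127 and 0.0869). At 1 h the preset call of camera was also lost with a further quantile normalization (adjusted p = 0.0860), the mean of probe sets (0.0550) and no variance trend (0.0649). It was lost as well without either treated array or replicate 2 of the untreated arrays. At 3 h it was lost without replicate 2 of the untreated arrays. In the direction of the 1 h call, Bcl2l11 was higher by 1.98, 1.27, 0.78 and 0.57 at 1, 3, 6 and 10 h and Bmf by 1.41, 1.45, 1.22 and 0.85 (SE 0.08 for both), while Bbc3, a p53 target, was lower at 3 h, with −0.87 ± 0.10.

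Groups of genes that share the stem of a symbol were tested after the data were seen, with 116 stems of at least 15 genes. With TGFβ1 at 1, 3, 6 and 10 h, 7, 1, 3 and 5 stems were called with the preset correlation, and 1, 0, 0 and 0 with an estimated one as well. Of 16 Klf genes 6 rose and 1 fell at 1 h (adjusted p = 2.94e-08, and 0.0188 with an estimated correlation). Of 47 Mrpl genes for mitochondrial ribosomal proteins 15 fell and 1 rose at 10 h (adjusted p = 2.93e-04; adjusted p = 0.710 with an estimated correlation).

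Across 18194 genes, the TGFβ1 effect and the change of untreated cells were compared where the comparisons share no arrays, a choice made after the data were seen. The correlation was −0.19 between the effect at 3 h and untreated cells at 10 h against 0 h, −0.14 for the effect at 6 h, and −0.15 between the effect at 10 h and untreated cells at 6 h against 0 h. Genes are not independent replicates, and no p is given.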
